A study of Mus musculus with 12 samples.

How the data were processed

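Gene expression was measured in the liver of 12 mice, 3 in each of 4 groups: wild-type (WT) and liver knock-out (KO) mice, fed or starved for 24 h. Per the labels' protocols, a piece of liver was kept in RNAlater, RNA was extracted with Trizol and cleaned on RNeasy columns, and labelled cDNA was made with the Ambion WT Expression kit and the Affymetrix whole-transcript labelling kit. The deposited values are log2 expression values per probe set. The authors' processing used RMA with oligo, and limma, per the submitters' processing notes; RMA corrects background, normalizes arrays to one another by quantiles and summarises the probes of a set. Versions, the array model, its annotation and a genome build were not given in the sources used here. A whole-transcript probe set reads a gene along its length, so a change limited to 1 exon can be diluted in its value. Quantile normalization at probe level removes a shift common to all genes, so differences are relative to the other genes of the array. No background signal per probe was used here, so a low value cannot be told from no expression.

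The annotated table has 28944 lines of 12 values. The series matrix holds the same values in all 347328 cells, so it gave no alternative. Of the lines, 5132 had no gene symbol and were left out of the main tests. For 1683 symbols with more than 1 line, the line with the highest mean over all arrays was used (Hmcn1 had 77 lines and Gapdh 36), which left 20719 genes. There were 701 lines whose 12 values equalled those of another line, among them 6 tested genes. Accessions of 19458 tested genes were found in a RefSeq gene table, where 1548 had another current symbol; the symbols of the deposited table are printed. Groups were taken from the sample labels. The title code of WT starved replicate 3 is irregular: the other starved mice have S and a number, WT starved replicate S3 among them. It was kept as labelled. Its median correlation with the arrays of its own group, 0.9777, was the lowest of all arrays, followed by 0.9787 for WT fed replicate F1. Each array is 1 mouse, and no value column lacked a sample.

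Tests were run with limma 3.58.1 in R 4.3.3 on the deposited log2 values, with lmFit and eBayes, equal weights, 4 group means in 1 fit and no covariate. The fit had 8 residual and 3.384 prior degrees of freedom, and the median residual SD was 0.186. The 7 contrasts were KO against WT in fed and in starved mice, starved against fed in WT and in KO mice, their interaction (the KO minus the WT response to starvation), and the averaged genotype and starvation effects. P-values were adjusted by Benjamini-Hochberg over all genes of a contrast and called under 0.05. Before the data were examined, the design, the alternatives, 36 pathway lists and 11 cell type marker lists were fixed; 1224 of their 1243 members were found. Lists were tested with camera at a preset correlation of 0.01 and with an estimated one, and with fry; their p-values were adjusted over the 47 lists of a contrast. Correlations across genes carry a jackknife SE over arrays. The number of arrays limits the precision: the median SE was 0.15 for a difference of 2 groups, 0.212 for the interaction and 0.106 for an averaged effect.

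Named genes were chosen by a rule fixed with the design. For each contrast these were the 8 largest rises and 8 largest falls among genes past the threshold whose groups did not overlap, leaving out predicted models and large receptor or small RNA families. Up to 4 members of each list with the smallest adjusted p among those past the threshold were added. Where fewer than 8 passed, the 4 genes with the smallest unadjusted p per direction were named by value only. Lamp2 was always named, and members of a list under discussion could be named by value.

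The test was checked on simulated data with the means and spread of the real genes, of which 200 were changed. The simulated noise was independent for each gene and array, without the differences between arrays that many real genes share. Of 2-fold changes it found 90% between fed genotypes, 82% between starved ones, 84% for starvation in each genotype, 46% for the interaction, and 98% and 94% for the averaged genotype and starvation effects. False calls made up 3.07% to 7.22% of the calls. These shares hold for such independent noise and can differ in the real arrays. Alternatives changed 1 choice at a time: all lines or the mean of a symbol's lines, filters on dim genes at the 25th percentile and the median, cyclic loess, median centring, array weights, eBayes with trend and robust options, only the 2 groups compared, the number in the sample title as a random block, a 1.5-fold limit, and leaving out each array. Added after seeing the data were a block for arrays with a wide or narrow spread of values, the mean of small RNA genes as a covariate, and fits within arrays of 1 spread. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Coordinates and the deleted exon were not analysed here, and single values of some list members are not reported here.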

Results

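Transcripts were measured in the livers of 12 mice, 1 array per animal, in a design that crossed 2 genotypes with 2 feeding states. The knock-out (KO) mice carried Albumin-Cre, which is active in hepatocytes, and loxP sites around an alternative last exon of Lamp2. Lamp2 is a lysosomal membrane protein, and the isoform ending in that exon is the receptor of chaperone-mediated autophagy, the pathway that carries single cytosolic proteins into lysosomes. Wild-type (WT) and KO mice were either fed chow or starved for 24 h with free access to water, which gave 4 groups of 3 mice: WT fed, WT starved, KO fed and KO starved. The comparisons ask what loss of this pathway changes in the liver of fed and of starved mice, what starvation changes in each genotype, and whether the response to starvation differs between them. All values are deposited log2 expression values, so a difference of 1 is a 2-fold change; 20719 genes were tested, and the number of arrays limits the precision. The median 95% confidence interval of a difference between 2 groups was 0.33 wide on either side, and that of the interaction 0.47.

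Lamp2 itself was read by 1 gene-level probe set, and its level was similar in all arrays. It measured 12.61, 12.24 and 12.25 in the WT fed mice, 12.68, 12.49 and 12.54 in the WT starved mice, 12.51, 12.81 and 12.49 in the KO fed mice, and 12.33, 12.56 and 12.60 in the KO starved mice. The KO minus WT difference of Lamp2 was 0.24 in fed mice (SE 0.14) and -0.07 in starved mice (SE 0.14), with a limma adjusted p of 1 in each. Which exons this probe set covers is not given in the sources used here. The value therefore checks neither the deletion nor the labels.

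In WT liver Cyp4a14, a fatty acid omega-hydroxylase, rose with starvation 34.6-fold, from 8.70 in fed to 13.82 in starved mice (SE of the log2 difference 0.39, n = 3 per group, adjusted p = 0.000342). Its relatives Cyp4a31 and Cyp4a10 rose 7.33-fold and 5.66-fold. Of the 29 measured targets of PPAR-alpha, the nuclear receptor that turns on hepatic fatty acid oxidation, 8 rose, 0 fell and 21 did not pass the test; adjusted over the list alone, 20 rose and 1 fell. Angptl4, a lipoprotein lipase inhibitor, rose by 1.61 (SE 0.30) and the fasting hormone Fgf21 by 0.98 (SE 0.17). The list's mean difference was 1.43, and camera called it higher with an adjusted p of 6.82e-19 at the preset correlation; the adjusted p was 0.224 with an estimated correlation. Of 23 genes of mitochondrial fatty acid oxidation and ketogenesis, Eci2 and Decr1 rose, by 0.86 and 0.57, and 0 fell; 13 rose adjusted over the list alone (mean 0.60, camera adjusted p = 1.15e-11, adjusted p = 0.224 with an estimated correlation). Among 19 lipid droplet and lipolysis genes 3 rose, over all genes as over the list alone: the triglyceride lipase Pnpla2 by 1.89, the lipid droplet protein Cidec by 2.85 and Plin5 by 1.34 (list mean 0.57, camera adjusted p = 6.05e-05, adjusted p = 0.224 with an estimated correlation). Apoa4, an apolipoprotein, rose by 3.02 (SE 0.36).

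Genes of lipid synthesis fell in the same WT livers. Of 25 cholesterol synthesis genes 7 fell and 0 rose, and 19 fell adjusted over the list alone. Mvd, the mevalonate decarboxylase, fell by 1.11 (SE 0.15, adjusted p = 0.00834), as did Tm7sf2 (-1.52) and Acat2 (-0.84). The list mean was -1.02 (camera adjusted p = 2.85e-17, adjusted p = 0.224 with an estimated correlation). Among 27 genes of fatty acid and triglyceride synthesis 6 fell and 1 rose, and 9 fell and 2 rose adjusted over the list alone. Thrsp, a lipogenic nuclear protein, fell by 3.57 (SE 0.59), as did the regulator Srebf1 (-1.74, SE 0.25), Aacs (-1.75) and Acss2 (-0.87). That list's mean was -0.50 (camera adjusted p = 4.06e-05, adjusted p = 0.37 with an estimated correlation), and -0.33 without WT fed replicate F1.

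In WT mice Igfbp1, an insulin-repressed binding protein, rose with starvation by 3.14 (SE 0.57), Igfbp2 by 1.18, and the coactivator Ppargc1a by 2.04 (SE 0.42). Ppargc1a was the only 1 of 17 gluconeogenesis genes past the threshold over all genes, against 6 adjusted over the list alone; the list mean was 0.80 (camera adjusted p = 4.11e-09, adjusted p = 0.224 with an estimated correlation). Of 24 glucocorticoid and FOXO targets 4 rose and 0 fell, or 6 and 1 adjusted over the list alone, with a mean of 0.78 (camera adjusted p = 0.000442, adjusted p = 0.37 with an estimated correlation). Those were Igfbp1, Per1, the siderophore-binding protein Lcn2 and the metallothionein Mt2. Within the clock list of 21 genes Per1, Nr1d2 and Gm129 rose, by 1.41, 1.44 and 2.88, and Nfil3 fell by 0.92; 6 rose and 4 fell adjusted over the list alone (mean 0.33, camera adjusted p = 0.0363, adjusted p = 0.734 with an estimated correlation). Asl of the urea cycle rose by 1.22 as the only 1 of 39 genes of amino acid catabolism and the urea cycle, against 6 higher and 2 lower adjusted over the list alone (mean 0.31, camera adjusted p = 4.06e-05, adjusted p = 0.603 with an estimated correlation). The call of that list was lost without WT fed replicate F2 (mean 0.11, camera adjusted p = 0.0508). That of the clock list was lost without WT fed replicates F2 (0.22) or F4 (0.26), WT starved replicate S4 (0.19), or KO fed replicates F6 or F8, and its mean was 0.50 without WT fed replicate F1.

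Of 42 proteasome genes in WT starved liver Psmd9, Psmd12 and Psmc3 rose, by 0.86, 0.63 and 0.52, and adjusted over the list alone 15 rose and 1 fell; the list mean was 0.26 (camera adjusted p = 3.61e-08, adjusted p = 0.224 with an estimated correlation). Of 39 macroautophagy genes the mitophagy receptor Bnip3 rose by 1.27 and the autophagosome protein Map1lc3b by 0.82, with Wipi1 as the third adjusted over the list alone (mean 0.24, camera adjusted p = 0.0017, adjusted p = 0.573 with an estimated correlation). Among 53 lysosomal genes the protease Ctsl rose by 0.97 (SE 0.15, adjusted p = 0.0116), and Idua was the second adjusted over the list alone (mean 0.21, camera adjusted p = 0.00627, adjusted p = 0.734 with an estimated correlation). The lysosomal call was lost without WT fed replicate F2 (mean 0.06) or WT starved replicate S3 (0.11), and the mean was 0.35 without WT fed replicate F1 and 0.355 without WT starved replicate 3. The macroautophagy mean was 0.15 without WT fed replicate F2 and 0.37 without WT starved replicate 3. In the chaperone-mediated autophagy list of 17 genes 0 passed, over all genes or over the list alone. Its mean was 0.16 with a camera adjusted p of 0.17. It was called without WT fed replicate F1 (mean 0.30, camera adjusted p = 0.0338) or WT starved replicate 3 (mean 0.32, camera adjusted p = 0.0144). These are the only WT fed array with a wide spread of values and the only WT starved array with a narrow one. The list's mean was 0.05 among wide and -0.02 among narrow WT arrays. With array spread as a block its camera adjusted p was 0.571. Hspa8, the chaperone that picks the substrates, stood 0.41 higher with an adjusted p of 0.355.

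Other groups moved in WT starved liver as well. The male-biased list of 22 genes had 5 that fell and 0 that rose, and 6 that fell adjusted over the list alone. Hsd3b5, a steroid dehydrogenase, fell by 3.75 (SE 0.52, adjusted p = 0.00834), as did the fatty acid elongase Elovl3 (-2.05), Slco1a1 (-1.84) and Nudt7 (-1.18). The list mean was -0.66 (camera adjusted p = 1.61e-07, adjusted p = 0.224 with an estimated correlation). Of 25 female-biased genes 4 rose: Cyp17a1 by 2.85, Acot3 by 2.52, Nipal1 by 2.35 and Fmo2 by 2.19. Adjusted over the list alone 9 rose and 3 fell, and the mean of 0.58 stood far above the median of 0.05 (camera adjusted p = 0.00708, adjusted p = 0.224 with an estimated correlation). Of 36 acute phase and inflammation genes Lcn2 rose by 3.68 (SE 0.53), Mt2 by 4.17 and Mt1 by 3.07, while Hamp2 fell by 1.86; 9 rose and 1 fell adjusted over the list alone (mean 0.66, camera adjusted p = 6.16e-06, adjusted p = 0.37 with an estimated correlation). Without WT starved replicate 3 that mean was 0.44 (camera adjusted p = 0.0105). The metallothioneins bind zinc and copper. Nr0b2, a nuclear receptor that represses bile acid synthesis, fell by 1.35 (SE 0.15, adjusted p = 0.00257). Rab30, a small GTPase, rose by 3.00, and Serpina4-ps1, Cyp2c55, Hsd3b2, Clec2h and Klk1b4 fell, with differences of -3.64, -2.65, -2.59, -2.44 and -2.35. The red blood cell genes Alas2 and Car1 fell (-1.65 and -2.41), with no call of their list of 16 (mean -0.25, camera adjusted p = 0.258).

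In all, limma with all 4 groups in 1 fit called 292 genes between starved and fed WT mice, 137 higher and 155 lower. Of these, 267 changed at least 1.5-fold, and in all 292 the values of the 3 starved mice lay apart from those of the 3 fed mice. Over the 20719 genes that was so for 13%, where chance gives 10%. Camera called 24 of 47 lists, 16 higher and 8 lower, and 0 of them with an estimated correlation; fry, which asks whether a list moves on balance in 1 direction, called 9. The count of genes fell to 11 when only these 6 arrays entered the fit, and it ran from 64 without WT starved replicate S4 to 659 without WT starved replicate 3.

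**Figure D1:**
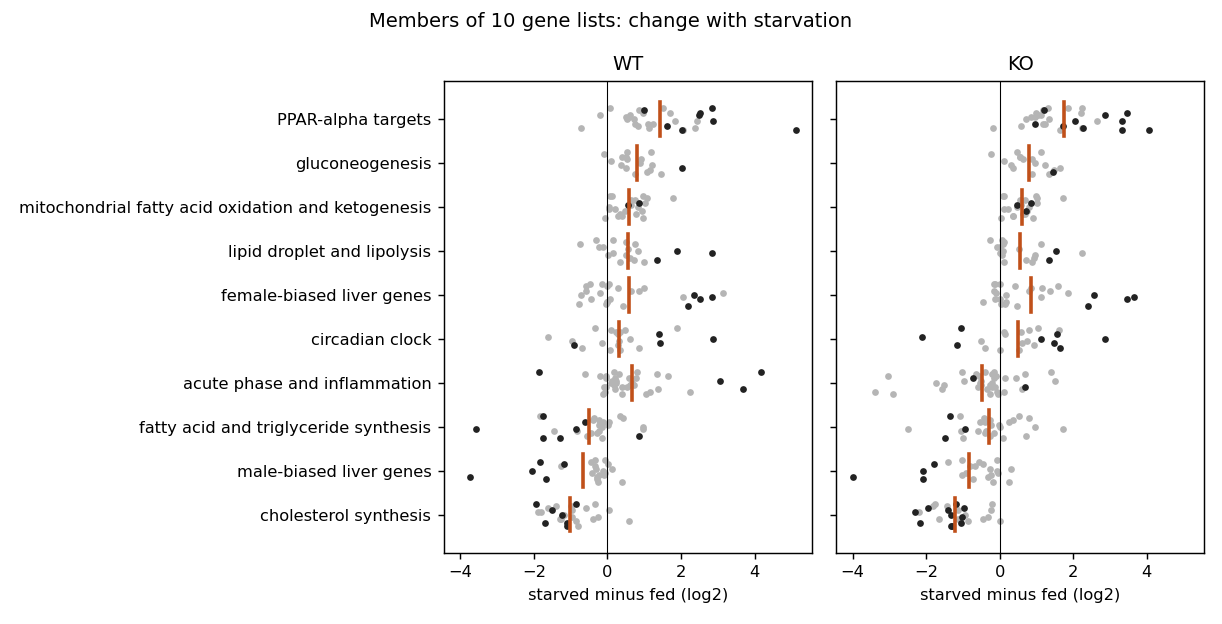
Mean log2 difference, starved minus fed, of the members of gene lists (vertical axis, list names) in WT mice (left) and KO mice (right); each dot is a gene, black where its adjusted p was under 0.05 and grey otherwise, and each vertical line is the list's mean. The PPAR-alpha targets have means of 1.43 and 1.74 and the cholesterol synthesis genes -1.02 and -1.21.

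In KO mice Cyp4a14 rose with starvation 16.7-fold (log2 difference 4.06, SE 0.39, n = 3 per group, adjusted p = 0.00112), and Mfsd2a, a transporter of lysophosphatidylcholine, 14.3-fold, from 7.97 to 11.82. Of the 29 PPAR-alpha targets 10 rose and 0 fell, and 24 rose adjusted over the list alone; the acyl-CoA thioesterases Acot1 and Acot3 rose by 3.32 and 3.48, Cyp4a31 by 3.32 and Cyp4a10 by 2.87. The list mean was 1.74 (camera adjusted p = 1.42e-37, adjusted p = 0.0977 with an estimated correlation). Of 23 fatty acid oxidation and ketogenesis genes Eci2, Eci1 and Decr1 rose, by 0.86, 0.70 and 0.46, and 11 rose adjusted over the list alone (mean 0.62, camera adjusted p = 1.48e-17, adjusted p = 0.139 with an estimated correlation). The lipid droplet genes Plin5 and Pnpla2 rose by 1.34 and 1.54, with 6 of 19 higher adjusted over the list alone (mean 0.55, camera adjusted p = 1.02e-06, adjusted p = 0.136 with an estimated correlation).

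Among the lipid synthesis genes of KO mice, 11 of 25 cholesterol genes fell and 0 rose, and 20 fell adjusted over the list alone. Idi1 fell by 2.30, as did Fdps (-2.17, SE 0.35, adjusted p = 0.0141), Dhcr7 (-1.32) and Mvd (-1.29); the list mean was -1.21 (camera adjusted p = 8.84e-26, adjusted p = 0.0977 with an estimated correlation). Of 27 fatty acid and triglyceride synthesis genes Srebf1, Aacs and Acss2 fell (-1.48, -1.36 and -0.94), and 0 rose; 8 fell and 3 rose adjusted over the list alone (mean -0.28, camera adjusted p = 0.00488, adjusted p = 0.491 with an estimated correlation). That call was lost without KO fed replicate F6 (mean -0.18) or KO starved replicate S5 (-0.135). The row named Gm6484, whose current name is Angptl8 and which encodes an insulin-induced inhibitor of lipoprotein lipase, fell by 2.08.

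The male-biased list fell in KO starved mice too, with 4 of 22 genes lower and 10 adjusted over the list alone. Hsd3b5 fell by 3.99 (SE 0.52, adjusted p = 0.00515), as did Selenbp2 (-2.09), Elovl3 (-2.07) and Nudt7 (-1.79); the list mean was -0.83 (camera adjusted p = 1.22e-12, adjusted p = 0.0664 with an estimated correlation). Of 25 female-biased genes Cyp17a1, Acot3, Nipal1 and Fmo2 rose, by 3.65, 3.48, 2.57 and 2.41, and 9 rose adjusted over the list alone. This list, with a mean of 0.85, held its call with an estimated correlation (adjusted p = 0.0456, against 9.28e-08 at the preset value). In the clock list Per1, Nr1d2 and Dbp were among 5 that rose, by 1.57, 1.47 and 1.64, and Nfil3 and Arntl among 3 that fell (-1.17 and -1.05); 10 rose and 3 fell adjusted over the list alone (mean 0.50, camera adjusted p = 1.02e-05, adjusted p = 0.45 with an estimated correlation). Gpt2 rose by 1.46 as the only 1 of 17 gluconeogenesis genes, with 10 adjusted over the list alone (mean 0.81, camera adjusted p = 1.57e-12, adjusted p = 0.15 with an estimated correlation).

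Several further genes changed in KO starved mice. Of 39 genes of the unfolded protein response and ATF4 targets, the chaperone genes Sdf2l1 and Pdia6 were among 4 that fell (-1.93 and -1.08), and Cyp4a14 and Fgf21 were the 2 that rose; 5 rose and 7 fell adjusted over the list alone, and the list was not called (mean -0.10, camera adjusted p = 0.21). Of 36 acute phase and inflammation genes Orm1 fell by 0.73 and Nfkbia rose by 0.70, with 2 higher and 5 lower adjusted over the list alone (mean -0.47, camera adjusted p = 0.00381, adjusted p = 0.492 with an estimated correlation). Of the 42 proteasome genes Psmd9 rose by 0.76, with 4 higher and 1 lower adjusted over the list alone (mean 0.14, camera adjusted p = 7.39e-05, adjusted p = 0.454 with an estimated correlation). Bnip3 and Map1lc3b rose by 1.21 and 0.69 among the 39 macroautophagy genes, over all genes as over the list alone (mean 0.19, camera adjusted p = 0.000879, adjusted p = 0.48 with an estimated correlation). Of 53 lysosomal genes 0 passed over all genes and 1, Ctsl, over the list alone (mean 0.20, camera adjusted p = 0.000107, adjusted p = 0.511 with an estimated correlation), and of 17 chaperone-mediated autophagy genes 0 passed either way (mean 0.16, camera adjusted p = 0.114). Without KO fed replicate F6 the chaperone-mediated autophagy list was called (mean 0.325, camera adjusted p = 0.00388), as it was without KO starved replicate S5 (0.275, camera adjusted p = 0.0166). These are the only wide KO fed and the only narrow KO starved array. That list's mean was -0.05 among wide and 0.10 among narrow KO arrays, and its camera adjusted p with array spread as a block was 0.61. The unfolded protein response list was called lower without KO fed replicate F8 (mean -0.28), the acute phase call was lost without KO fed replicate F6 (-0.34), and the macroautophagy call without KO fed replicate F8 (0.10, and 0.30 without F6). The proteasome mean was 0.09 without KO fed replicate F6 and 0.08 without KO starved replicate S5, and the lysosomal mean 0.335, 0.0959, 0.326 and 0.125 without KO fed replicates F6 and F8 and KO starved replicates S5 and S7. Slc16a5, a monocarboxylate transporter, rose by 3.53, Rgs16 by 3.29 and Por, the electron donor of cytochromes P450, by 2.25, while Serpina4-ps1, Cyp2c55, Kcnt2, Hsd3b2 and Hsd3b4 fell, with differences of -4.07, -3.12, -2.82, -2.63 and -2.22.

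For starved against fed KO mice limma called 212 genes, 101 higher and 111 lower, of which 200 changed at least 1.5-fold. All 212 had values that lay apart between the groups of 3, as did 16.5% of all genes against 10% by chance. Camera called 25 of 47 lists, 17 higher and 8 lower, 1 of them with an estimated correlation, and fry called 6. The count was 357 with only these 6 arrays in the fit, and it ran from 45 without KO fed replicate F5 to 344 without WT starved replicate 3.

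**Figure D2:**
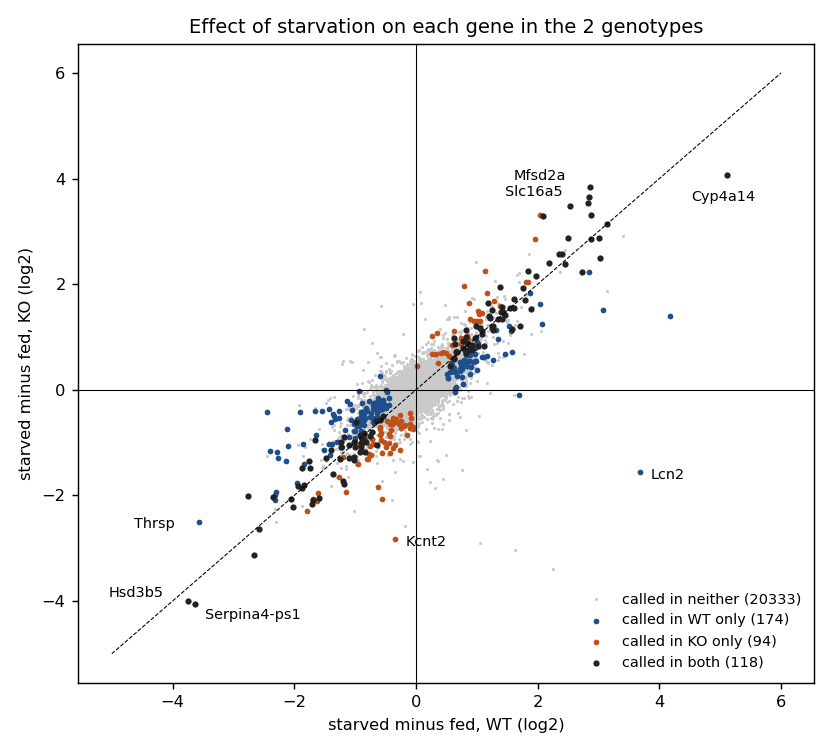
Log2 difference, starved minus fed, of each of 20719 genes in WT mice (horizontal axis) and in KO mice (vertical axis); colours mark genes called in WT mice only (174), in KO mice only (94), in both (118) or in neither (20333), and the broken line marks equal differences. Lcn2 lies far from that line, at 3.68 in WT and -1.56 in KO mice.

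The starvation responses of the genotypes overlapped. Of the called genes, 67 rose and 51 fell in both, where lists of these sizes drawn independently would share 0.668 and 0.83. The comparisons have no array in common, but they share the estimate of each gene's spread over all arrays. Both also have more arrays with a wide spread of values among starved than among fed mice, as described below. The overlap is therefore not that of independent experiments. Across genes, which are not independent replicates, the WT and KO differences had a Pearson r of 0.729 and a Spearman rho of 0.571. Of the 174 genes called in WT mice alone, 170 had the same sign in KO mice, and all 94 called in KO mice alone had the same sign in WT mice. The interaction was not called for any of these genes; its unadjusted p was under 0.05 for 44 and 27 of them. The responses of these genes were therefore not shown to differ.

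Lcn2 had the smallest unadjusted p of any gene for the interaction, though not the largest difference. Its mean level was 8.44 in WT fed, 12.12 in WT starved, 10.93 in KO fed and 9.37 in KO starved mice, an interaction of -5.24 (SE 0.75) with an adjusted p of 0.409. The 3 WT starved mice spread from 10.64 to 13.23, and without WT starved replicate S4, the lowest, Lcn2 passed (-5.98, adjusted p = 0.00237). Fgl1, a hepatocyte protein released in inflammation, had an interaction of -1.78 (SE 0.35) and Arv1 of -0.67. On the other side stood Tsc22d3, a glucocorticoid-induced gene, at 0.96 (SE 0.22), Spc25 at 0.86, Nr0b2 at 0.84 and Ccng2 at 0.51, each with an adjusted p of 1. As a group the 36 acute phase genes had a mean interaction of -1.14: the serum amyloids Saa1 and Saa2 stood at -4.66 (SE 1.66) and -5.65 (SE 1.83), and Orm2 at -3.95 (SE 0.98). Without WT starved replicate 3, the highest, these 3 stood at -2.90, -3.84 and -2.99. Over all genes 0 members passed and adjusted over the list alone 2 did, Lcn2 and Orm2; camera called the list lower (adjusted p = 4.99e-18, adjusted p = 0.425 with an estimated correlation).

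Limma called 0 genes for the interaction, with 422 at an unadjusted p under 0.05 where chance gives 1036, but 1196 with array spread as a block. Camera called 14 of 47 lists, 9 higher and 5 lower (6 without WT fed replicate F1, 20 without WT fed replicate F2), 0 of them with an estimated correlation, and fry called 0. On simulated data of the same size and spread, the interaction test found 92% of 4-fold and 46% of 2-fold changes. That noise was independent between genes, so these shares may not hold for the real arrays.

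**Figure D3:**
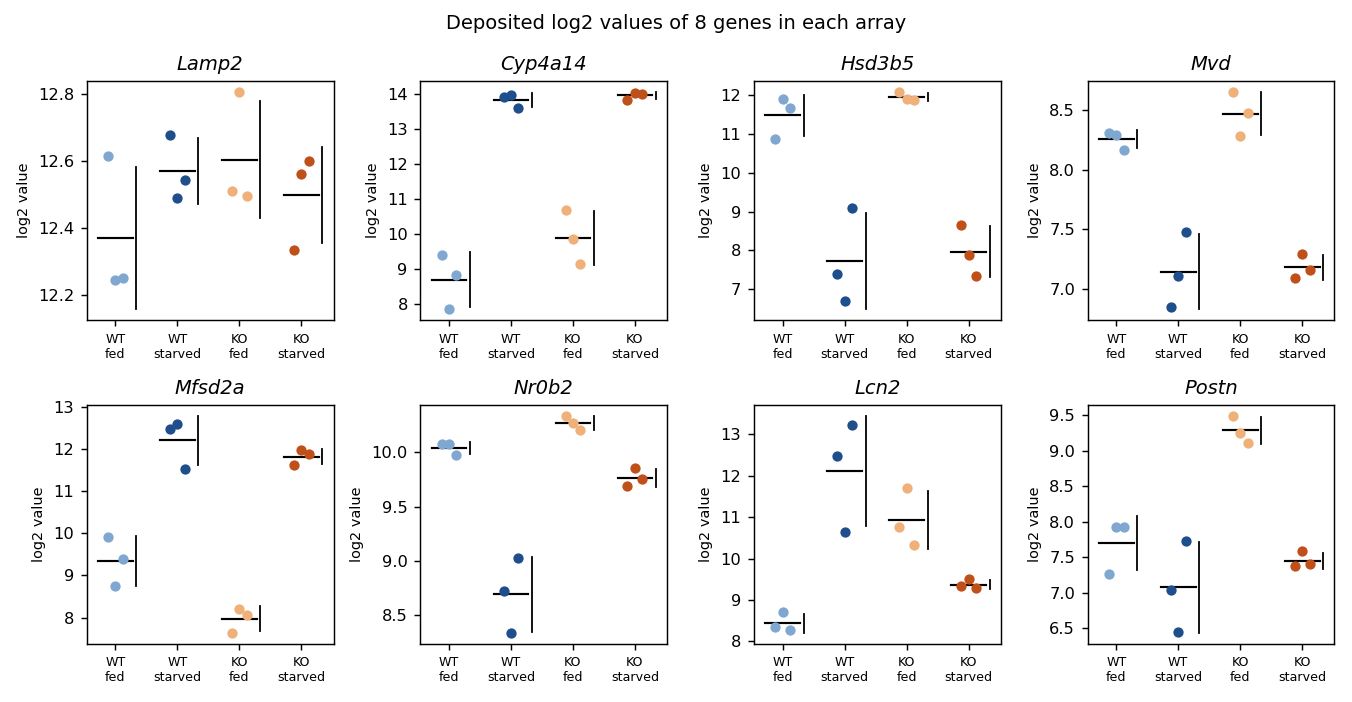
Log2 expression of 8 genes (vertical axes) in the 4 groups (horizontal axes); dots are single mice, horizontal lines group means and vertical bars the mean ± SD, n = 3. Lamp2 stays between 12.24 and 12.81 in all mice, Cyp4a14 rises with starvation in both genotypes, and Lcn2 has means of 8.44, 12.12, 10.93 and 9.37.

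In fed mice no gene was called between KO and WT. By value, Postn, a matrix protein of fibroblasts, stood highest relative to its error: 7.70 ± 0.38 in WT and 9.29 ± 0.20 in KO mice (mean ± SD, n = 3), a log2 difference of 1.58 (SE 0.28) with an adjusted p of 1. Golph3l was 0.73 higher, Efemp1 0.62 and Sgce 0.59. Mfsd2a had a difference of -1.38 (SE 0.32), Tuba3b of -0.73, Ccdc8 of -0.50 and Kcnj16, a potassium channel, of -0.41, again with an adjusted p of 1. Limma's smallest adjusted p over all genes was 1. At an unadjusted p under 0.05 stood 603 genes where chance gives 1036, but 1471 with array spread as a block in the fit. The low count therefore does not show that fewer genes than by chance differ. The groups of 3 lay apart for 7.97% of genes against 10% by chance.

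Lists were called between fed KO and WT mice at the preset correlation, 7 higher and 5 lower of 47, and 0 by fry or with an estimated correlation. Interferon response genes lay higher in KO mice (34 of 37 above 0, mean 0.27, camera adjusted p = 5.85e-08), as did acute phase genes (30 of 36, mean 0.47, camera adjusted p = 2.34e-07), proteasome genes (36 of 42, mean 0.11, camera adjusted p = 9.4e-05) and genes of the unfolded protein response and ATF4 (30 of 39, mean 0.20, camera adjusted p = 0.000484). Cholesterol synthesis (mean 0.16), male-biased (0.14) and sex chromosome genes (0.14) were called higher as well. In every array the Y-linked gene Ddx3y lay at 9.09 to 9.97 and the female-expressed Xist at 3.86 to 4.58. By these genes the mice of all groups read as male. Gluconeogenesis genes lay lower (mean -0.25), with G6pc, the last enzyme of glucose release, at -0.63 (SE 0.23), and so did fatty acid and triglyceride synthesis (-0.24), clock (-0.18), amino acid catabolism and urea cycle (-0.14) and cell cycle genes (-0.09). All 12 calls had an adjusted p of 0.929 with an estimated correlation, and 9 of them were lost when 1 or another array was left out. Without WT fed replicate F1 the means of amino acid catabolism, clock, fatty acid synthesis and gluconeogenesis genes were 0.00538, -0.00774, -0.06 and -0.07. Those of cholesterol synthesis and sex chromosome genes were 0.05 and 0.05 without WT fed replicate F2, those of the unfolded protein response and male-biased genes 0.04 and 0.08 without KO fed replicate F6, and that of cell cycle genes -0.06 without WT fed replicate F4. The interferon mean was 0.17 without KO fed replicate F5, and the proteasome mean 0.07 without WT fed replicate F2 and 0.17 without F4, with their calls kept. In these lists 0 members passed over all genes, and adjusted over the list alone 1 acute phase gene did, Lcn2, at 8.44 in WT and 10.93 in KO mice.

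In starved mice the gene with the smallest p between genotypes was Nr0b2, at 8.70 in WT and 9.77 in KO mice, a difference of 1.07 (SE 0.15) with an adjusted p of 0.292. Lcn2 had a difference of -2.75 (SE 0.53, adjusted p = 1), Arl13b of -0.73, Hist1h1c of -0.64 and Olig1 of -0.62. Ahsp, the chaperone of alpha-globin, was 1.56 higher in KO mice (SE 0.37, adjusted p = 1), Cyp2a22 1.27 and Spc25 0.68. Limma called 0 genes, with 744 at an unadjusted p under 0.05 where chance gives 1036, but 1771 with array spread as a block. The groups lay apart for 9.81% of genes against 10% by chance. Leaving out single arrays gave calls: Nr0b2 without WT starved replicate 3 (1.24, adjusted p = 0.0287), Lcn2 without WT starved replicate S4 (-3.49, adjusted p = 0.0254), and Ahsp (2.10, adjusted p = 0.0243), Slc4a1 (1.14) and Rgs16 (1.95) without KO starved replicate S5. These 5 genes were singled out after their values were seen.

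Camera called 8 of 47 lists between starved KO and WT mice, 5 higher and 3 lower, and 0 with an estimated correlation or by fry. The acute phase list, higher in fed KO mice, was lower in starved ones: 32 of 36 genes below 0, mean -0.67, camera adjusted p = 9.41e-10, adjusted p = 0.833 with an estimated correlation, and 1 gene, Lcn2, lower adjusted over the list alone. Red blood cell genes lay higher (mean 0.40, camera adjusted p = 1.66e-07, adjusted p = 0.747 with an estimated correlation; 1 gene, Ahsp, adjusted over the list alone), as did PPAR-alpha targets (mean 0.31, camera adjusted p = 5.72e-06). Drug-metabolising enzymes (mean 0.10), sinusoidal endothelial genes (0.09) and NRF2 targets (0.07) were also called higher, and gluconeogenesis (-0.24) and amino acid catabolism genes (-0.16) lower. The last 6 lists had an adjusted p of 0.955 with an estimated correlation and 0 members adjusted over the list alone. When 1 or another array was left out all 6 of them lost their call, and without WT starved replicate 3 the means of PPAR-alpha targets and sinusoidal endothelial genes were -0.10 and -0.06, that of NRF2 targets 0.04 and that of the acute phase list, still called, -0.445. Gluconeogenesis and amino acid catabolism stood at -0.10 and -0.07 without WT starved replicate S4, and drug-metabolising enzymes at 0.04 without KO starved replicate S6.

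Averaged over both feeding states, with 6 mice of each genotype, limma again called 0 genes between KO and WT. At an unadjusted p under 0.05 stood 963 genes, and 2028 with array spread as a block. Nr0b2 was 0.65 higher in KO mice (SE 0.11, adjusted p = 0.592), Postn 0.98, Sgce 0.44 and Rsl1 0.35; Kcnj16 stood at -0.39 (SE 0.06, adjusted p = 0.592), Smad7 at -0.45, Zc3h12d at -0.37 and Kctd17 at -0.32. Camera called 10 lists, 7 higher and 3 lower, all with an adjusted p of 0.926 with an estimated correlation; the interferon list had the smallest preset p (mean 0.20, camera adjusted p = 1.48e-06; 0.34 without WT starved replicate S3, and 0.13 without S4 or without 3). The genotype differences of fed and of starved mice had a Pearson r of 0.078 across genes (jackknife SE over arrays 0.282, Spearman rho 0.122), and 55.1% of genes had the same sign in both. The averaged genotype and starvation differences had an r of -0.0818 (jackknife SE 0.491, Spearman rho -0.0428). On simulated data the averaged test found 98% of 2-fold and 56% of 1.5-fold changes, and the test in fed mice 90% and 38%. These shares too hold for noise independent between genes, so 0 calls do not exclude changes of these sizes in the real arrays.

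Averaged over genotype, with 6 starved against 6 fed mice, limma called 1070 genes, 481 higher and 589 lower, of which 610 changed at least 1.5-fold. Members of the lists above that missed the threshold in single genotypes passed here. Of 29 PPAR-alpha targets 20 rose, and of 23 oxidation and ketogenesis genes 11 did. Cpt1a, which admits fatty acids into mitochondria, rose by 1.75 (SE 0.36, adjusted p = 0.0155), Pdk4, which blocks pyruvate oxidation, by 1.42 and the peroxisomal enzyme Ehhadh by 1.95. Of 17 gluconeogenesis genes 7 rose, G6pc by 0.71 among them; Pck1 stood 1.33 higher with an adjusted p of 0.0501. Of 25 cholesterol genes 19 fell, including Sqle (-2.04) and Insig1 (-1.86), and of 27 fatty acid and triglyceride synthesis genes 9 fell, including Scd1 (-1.45) and Fasn (-1.25), and 3 rose. Bnip3, Map1lc3b, Optn and Wipi1 of the 39 macroautophagy genes rose, as did Ctsl and Idua of the 53 lysosomal genes. Camera called 24 lists, 17 higher and 7 lower, 0 of them with an estimated correlation, and fry called 13. The count of genes ran from 625 without KO fed replicate F5 to 1608 without WT starved replicate 3.

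The arrays also differed in a way the groups do not explain. Their interquartile ranges ran from 2.62 to 3.06 without a clear gap. Divided at the median, the 6 wide arrays, at 2.97 to 3.06, were WT fed replicate F1, WT starved replicates S3 and S4, KO fed replicate F6 and KO starved replicates S6 and S7; the 6 narrow ones lay at 2.62 to 2.91. Each genotype has 1 wide array among its fed and 2 among its starved mice, so spread is balanced between genotypes but not between feeding states. These sets were defined from the values and are not the study's groups. The first principal component, the largest axis of variation among the arrays, held 47.9% of the variance. It correlated with the interquartile range at -0.81 and with the mean of small RNA genes at 0.71. As starved mice held more wide arrays, this component does not part spread from feeding. The mean level of 68 small nucleolar and Cajal body RNA genes was 7.49 in narrow and 6.88 in wide arrays. Within groups, narrow arrays stood higher by 1.03 in WT fed, 0.745 in KO fed and 0.623 in KO starved mice, but by 0.0985 in WT starved mice. WT starved replicate 3, the narrowest array, stood at 6.90, near the wide arrays.

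Values within these sets rest on few mice, with 1 per genotype among wide fed arrays and among narrow starved arrays. The PPAR-alpha mean of the starvation difference was 1.41 in wide and 0.81 in narrow WT arrays and 1.63 and 1.59 in KO arrays, and the cholesterol mean -1.53 and -0.37 in WT and -1.15 and -1.49 in KO arrays. The interferon mean between fed KO and WT mice was 0.23 and 0.30, and the acute phase mean 0.78 and 0.31 in fed and -0.39 and -1.24 in starved mice. Red blood cell genes differed between starved KO and WT mice by 0.60 among wide but by -0.01 among narrow arrays, PPAR-alpha targets by 0.03 and 0.88, and drug-metabolising enzymes by 0.23 and -0.14. Among lists called elsewhere, signs also differed for red blood cell genes in KO starvation (0.42 and -0.16) and for oxidative phosphorylation in averaged starvation (0.04 and -0.09). For genotype averaged over feeding they differed for PPAR-alpha targets (-0.08 and 0.49), male-biased genes (0.14 and -0.07) and the proteasome (-0.00378 and 0.116). With the set as a block in the fit, limma called 1225 genes for starvation in WT and 881 in KO mice. The same fit called 4 genes between fed KO and WT mice, named here after their values were seen: Postn (1.58), Mfsd2a (-1.38), Scgb1c1 (0.92) and Mir680-1 (0.74), each with an adjusted p of 0.0432.

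The block also changed calls of lists. In WT starvation 5 of 24 calls were lost: lysosome (camera adjusted p = 0.154, means of 0.08 among wide and 0.06 among narrow arrays), clock (0.213, means of 0.06 and 0.34), oxidative phosphorylation (0.0591), growth hormone, insulin and IGF axis (0.248) and stellate cell markers (0.0723). Interferon response (0.00392) and drug-metabolising enzymes (0.0312) were gained. Macroautophagy kept its call (0.0304), with means of 0.17 among wide and 0.09 among narrow arrays against 0.24 in all WT arrays. In KO starvation 6 of 25 were lost: macroautophagy (0.0637, means of 0.06 and 0.13), tricarboxylic acid cycle (0.0526), lipoprotein and fatty acid transport (0.0637), growth hormone, insulin and IGF axis (0.0637), cell cycle (0.101) and red blood cell markers (0.0987). Sinusoidal endothelial (0.00148), unfolded protein response and ATF4 (0.000804) and pericentral genes (0.0481) were gained. The lysosome list kept its call (0.0445), with means of 0.06 among wide and 0.08 among narrow arrays against 0.20 in all KO arrays. In averaged starvation lysosome (0.0508), oxidative phosphorylation (0.631), lipoprotein and fatty acid transport (0.102) and growth hormone, insulin and IGF axis (0.119) were lost, and sinusoidal endothelial (9.45e-07), cholangiocyte (0.0483) and immediate early genes (0.0333) gained. For genotype and the interaction 3 calls were lost: sex chromosome genes in fed mice (0.0544), hepatocyte markers averaged over feeding (0.104) and cell cycle in the interaction (0.0642). Gained there were macroautophagy in fed mice (0.0221) and averaged over feeding (0.0337), oxidative phosphorylation (0.00574) and periportal genes (0.0295) in starved mice, and sinusoidal endothelial genes in the interaction (0.00481).

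**Figure D4:**
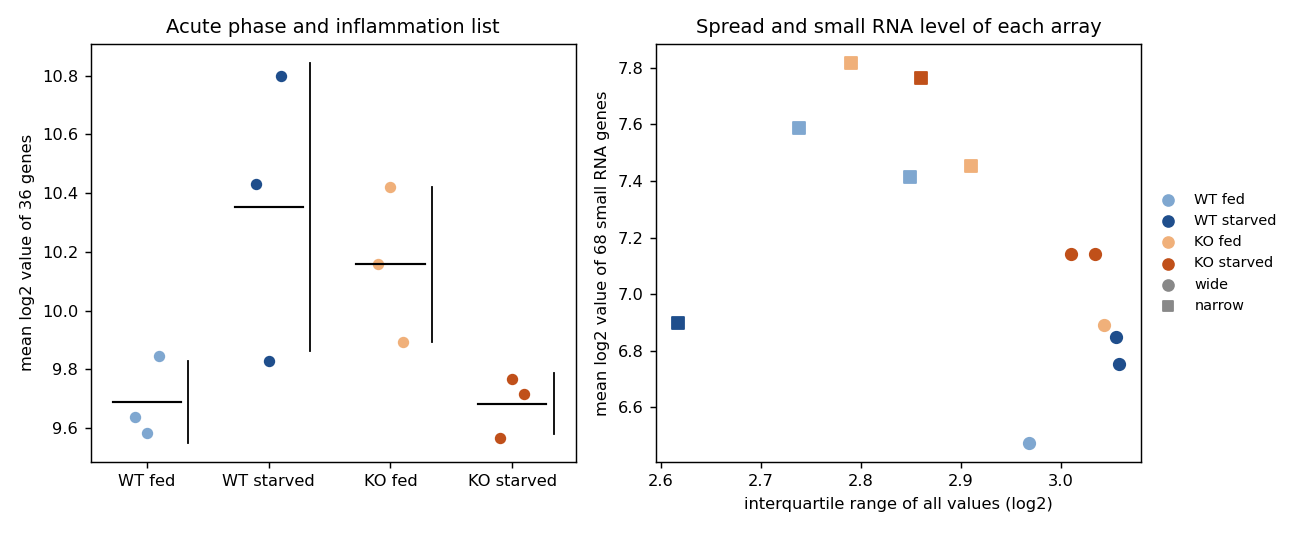
Left, the mean log2 value of 36 acute phase and inflammation genes in each mouse (dots) by group, with horizontal lines for group means and vertical bars for the mean ± SD, n = 3; right, the interquartile range of each array (horizontal axis, log2) against its mean of 68 small RNA genes (vertical axis, log2), circles for wide and squares for narrow arrays. The acute phase mean reaches 10.8 in WT starved replicate 3 and stays between 9.57 and 9.77 in KO starved mice.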

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

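For the acute phase list, the tests of single arrays, of array spread and of the largest of all lists were chosen after the interaction was seen. The exact permutation test and the splits of the arrays were fixed before. The interaction is the KO response to starvation minus the WT response.

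The response of 36 acute phase and inflammation genes to starvation differed between genotypes by a mean of -1.14. Camera's test of the difference passed at the preset correlation (adjusted p = 0.425 with an estimated correlation, fry adjusted p = 0.871). Saa2 (-5.65), Lcn2 (-5.24), Saa1 (-4.66) and Orm2 (-3.95) weighed most in this mean. Most members were smaller in size than the mean, and Hamp2, Nfkbia and Il6 were positive. The list mean was 9.637, 9.584 and 9.847 in WT fed mice, 10.43, 9.829 and 10.8 in WT starved, 10.16, 10.42 and 9.894 in KO fed, and 9.566, 9.766 and 9.716 in KO starved mice. A single array as the cause is argued against: leaving out WT starved replicate 3 moved the mean closest to 0, to -0.912. An effect of array spread that is equal in all groups cancels in this interaction, as spread is balanced between genotypes in each feeding state. An effect of spread that differs between groups stays open. The mean was -1.17 among wide and -1.55 among narrow arrays. These values rest on 1 mouse per genotype among wide fed and among narrow starved arrays, WT starved replicate 3 being 1 of them. A chance labelling of genotype is argued against: 2 of 400 relabellings within feeding state gave a mean as large (two-sided exact permutation p = 0.005, the smallest they can give), and 2 of 400 gave any of the 47 lists a mean as large in size, while the p adjusted list by list was 0.235, the smallest it can be for a single list at that p.

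The other 13 lists whose interaction camera called are given as values. Red blood cell markers had a mean of 0.417, PPAR-alpha targets 0.314, female-biased genes 0.273, drug-metabolising enzymes 0.244, fatty acid and triglyceride synthesis 0.222, circadian clock 0.174, NRF2 targets 0.161, oxidative phosphorylation 0.112 and cell cycle 0.0796. Negative means were found for the unfolded protein response and ATF4 targets (-0.324), sex chromosome genes (-0.252), interferon response (-0.152) and proteasome (-0.125). With an estimated correlation the adjusted p of these 13 ran from 0.479 to 0.981. Leaving out 1 array turned the mean of PPAR-alpha targets to -0.104 (WT starved replicate 3), of oxidative phosphorylation to -0.0472 (KO fed replicate F6) and of interferon response to 0.126 (WT starved replicate S3), and 12 of the 14 calls were lost without 1 or another array. Without WT fed replicate F1 the means of circadian clock, fatty acid and triglyceride synthesis and drug-metabolising enzymes were 0.000391, 0.0473 and 0.0729. Among wide and narrow arrays, again with lone mice, 3 of the 13 means differed in sign: red blood cell markers (0.704 and -0.0334), drug-metabolising enzymes (0.573 and -0.104) and cell cycle (0.136 and -0.0383). Far smaller among narrow arrays were fatty acid and triglyceride synthesis (0.424 and 0.0351), the unfolded protein response and ATF4 targets (-0.524 and -0.0943), circadian clock (0.286 and 0.0716), proteasome (-0.152 and -0.0176) and sex chromosome genes (-0.341 and -0.102). The other pairs were 0.225 and 0.786 for PPAR-alpha targets, 0.417 and 0.33 for female-biased genes, 0.245 and 0.135 for NRF2 targets, 0.167 and 0.141 for oxidative phosphorylation, and -0.12 and -0.142 for interferon response.

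Chance cannot be excluded for the number of lists with an interaction: 60 of 100 splits of the arrays called 14 or more, up to 29. Nor can it be for 10 lists of the averaged genotype effect, with 78 of 100 splits as large (highest 29), or for 24 lists of the averaged starvation effect, with 18 of 100 (highest 28). For genes, all 100 splits called at least the 0 of the interaction and all 100 at least the 0 of the averaged genotype effect. Their highest counts of 2368 and 2884 point to a structure of the arrays other than genotype; the split with 2884 set 5 of the 6 wide arrays on 1 side. For the 1070 genes of averaged starvation a chance split is argued against but not excluded, with 2 of 100 splits as large, the real one included. The other, with 1411, parted the WT arrays by spread and the KO arrays by feeding, in the reverse direction, so its calls hold the KO starvation difference as well. With spread as a block the real split called 2235.

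In the comparisons of 3 with 3 mice, the 10 splits are too few for a share under 0.05. The real count of genes was 292 in WT starvation (highest other 7; 1 of 10 as large), 212 in KO starvation (0; 1 of 10), 0 in KO against WT fed mice (0; 10 of 10) and 0 in starved mice (1; 10 of 10). The real count of lists was 24 in WT starvation (highest other 27; 3 of 10), 25 in KO starvation (23; 1 of 10), 12 in fed mice (25; 6 of 10) and 8 in starved mice (28; 8 of 10).

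Outside the named genes, lines without a gene symbol held signal: of 5132, limma called 15 for starvation in WT mice, 6 in KO mice and 65 averaged over genotype. In the genotype and interaction contrasts limma called 0 of them, with a smallest adjusted p of 1.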

How the results depend on the processing

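The fits with array spread or the small RNA mean were chosen after the data were seen; the others were planned. No named gene past the threshold changed sign in any alternative, while Lamp2, not past it, did in some. Of the called lists 22 changed direction in the test or the mean in 1 or more alternatives, none of them past the threshold there. The named genes kept direction and side of the threshold in 6347 gene and setting pairs, were weaker in 859, stronger in 39 and moved in 7. Counts of calls moved far more, and the causes were not tested, except that fits with fewer arrays have fewer degrees of freedom. Signal over background was not used here, so its limit on dim genes is unknown.

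With array weights limma called 1267 genes between fed KO and WT mice, 13 between starved ones, 5600 for WT and 7639 for KO starvation, 106 for the interaction, 170 for averaged genotype and 9499 for averaged starvation, and camera 9 lists for the interaction. Lamp2 then stood at 0.31 in WT starvation (adjusted p = 0.0373), 0.0313 in KO starvation and 0.17 in averaged starvation (adjusted p = 0.0385). Only the 2 groups compared gave 11 genes for WT and 357 for KO starvation. A 1.5-fold limit left 610 of averaged starvation. With the mean of a symbol's lines camera called 5 lists between starved genotypes.

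With the title number as a random replicate block limma called 934, 781 and 2228 genes for WT, KO and averaged starvation. After each gene's group mean was subtracted, same-numbered arrays correlated at -0.172 (F4 and S4), 0.454 (F5 and S5) and 0.532 (F6 and S6). F5 and S5 were both narrow and F6 and S6 both wide, while F4 was narrow and S4 wide. The correlations thus go with array spread as well as with the numbers. The numbers were not taken to pair the arrays, and whether some mark a shared step is unsettled. Lists were not run with this block.

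With spread as a block the counts were 4 for fed genotypes, 1225 for WT, 881 for KO and 2235 for averaged starvation, where Lamp2 stood at -0.032. With the small RNA mean as covariate they were 4 for fed genotypes (Zfp39, Mir122a, Lin7a and Tuba3b, seen after the fact), 752, 749 and 1964 for WT, KO and averaged starvation and 7 for averaged genotype. That fit called 24 lists between starved genotypes and 21 for averaged genotype. Lamp2 was 0.12 between starved genotypes and -0.0187 in averaged starvation, and the correlation of the genotype effects 0.491. The small RNA mean itself differed by genotype. It ran from 6.75 to 6.90 in WT starved and from 7.14 to 7.77 in KO starved mice, though fed ranges overlapped. Its slope is shared by the fed and starved genotype differences, so these lists and this correlation can come in part from the adjustment. Wide arrays alone leave 1 mouse in each fed arm, and narrow arrays alone 1 in each starved arm, assumed to vary like the other groups. Wide arrays alone gave 1 gene for fed genotypes and the interaction (Ctse in each), 1 for starved genotypes (Cyp2c39), 537 for WT starvation and 4 for averaged genotype, with Lamp2 at -0.0306 in WT and -0.13 in averaged starvation. Narrow arrays alone gave 19 genes for starved genotypes, 88 for WT starvation, 12 for the interaction, 5 for averaged genotype and 599 for averaged starvation, and 8 lists for the interaction.

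Lists changed direction between starved genotypes with the small RNA mean for gluconeogenesis (0.0387) and amino acid catabolism (0.0522), and among narrow arrays for drug-metabolising enzymes (-0.141), red blood cell markers (-0.0108) and, in the test alone, gluconeogenesis (-0.0386). For the interaction they did among narrow arrays for red blood cell markers (-0.0334), drug-metabolising enzymes (-0.104), cell cycle (-0.0383) and, in the test alone, proteasome (-0.0176), with the small RNA mean for oxidative phosphorylation (-0.0163) and with array weights for PPAR-alpha targets (-0.0255). For averaged genotype they did with array weights for proteasome (-0.00587), among wide arrays for proteasome (-0.00378) and PPAR-alpha targets (-0.0828), among narrow ones for male-biased genes (-0.0678), and with the small RNA mean for amino acid catabolism (0.00458) and periportal genes (0.0623). Red blood cell markers did in KO starvation among narrow arrays (-0.156), and oxidative phosphorylation in averaged starvation among wide arrays (0.0441).

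With 1 array left out the mean of amino acid catabolism ran from -0.342 to 0.00538 between fed genotypes (0.00538 without WT fed F1). Between starved ones PPAR-alpha targets ran from -0.103 to 0.526 and sinusoidal endothelial markers from -0.062 to 0.234 (both lowest without WT starved 3). For the interaction PPAR-alpha targets ran from -0.104 to 0.526 (lowest without WT starved 3), oxidative phosphorylation from -0.0472 to 0.224 (lowest without KO fed F6) and interferon response from -0.295 to 0.126 (highest without WT starved S3). For averaged genotype PPAR-alpha targets ran from -0.0512 to 0.266 (lowest without WT starved 3) and hepatocyte markers from -0.000466 to 0.0727 (lowest without WT fed F2).

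With an estimated correlation camera called 0 lists, except 1 in KO starvation. Fry called 9 in WT, 6 in KO and 13 in averaged starvation, and 0 elsewhere.

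Leaving out 1 array gave 0 to 0 genes for fed genotypes, and 0 to 3 for starved ones (3 without KO starved S5, 1 each without WT starved S4 and 3). WT starvation ran from 64 without WT starved S4 to 659 without WT starved 3 (78 without WT fed F4, 107 without F2, 159 without WT starved S3, 192 without KO fed F5, 154 without KO starved S6, 151 without S7). KO starvation ran from 45 without KO fed F5 to 344 without WT starved 3 (136 without F6, 130 without F8, 81 without KO starved S5, 51 without S6, 71 without S7). The interaction ran from 0 to 1 (WT starved S4), averaged genotype from 0 to 1 (Mme, WT fed F2) and averaged starvation from 625 without KO fed F5 to 1608 without WT starved 3 (687 without WT starved S4, 655 without KO starved S6, 689 without S7). Lists ran from 7 (WT fed F4) to 17 for fed genotypes, 6 to 19 for starved ones (19 without KO starved S5, 14 without WT starved S4), 21 to 27 for WT, 21 to 26 for KO and 23 to 28 for averaged starvation. For the interaction they ran from 6 to 20 (6 without WT fed F1 or KO fed F8, 8 without KO fed F5, 7 without KO starved S6), and for averaged genotype from 7 to 18 (18 without KO fed F8, 17 without WT fed F1, 16 without WT starved S3 or KO starved S5).

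With 1 array left out Lamp2 ran from 0.13 to 0.36 between fed and from -0.12 to 0.00981 between starved genotypes (0.00981 without KO starved S5). It ran from 0.14 to 0.32 in WT, -0.16 to -0.00432 in KO and 0.02 to 0.11 in averaged starvation, -0.43 to -0.21 for the interaction and 0.03 to 0.14 for averaged genotype. The correlation of the genotype effects ran from -0.073 to 0.189, and that of averaged genotype and starvation from -0.367 to 0.186.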

Other observations

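The test of gene length and the fit with array spread as a block were chosen after array spread was seen; the other tests of array spread and weights were fixed before their results. Of the markers of other liver cells, 23 sinusoidal endothelial ones were called lower in WT starvation (mean -0.175, camera adjusted p = 0.03, adjusted p = 0.734 with an estimated correlation) and not in averaged starvation (mean -0.11, camera adjusted p = 0.135). The WT call was lost without WT starved replicate 3 (mean -0.0216), WT fed replicate F1 (-0.0462) or F4 (-0.155), and the mean was -0.322 without WT fed replicate F2 and -0.269 without WT starved replicate S3. With array spread as a block the camera adjusted p was 3.96e-08 in WT and 9.45e-07 in averaged starvation, while 5 of the 24 lists called in WT and 4 of the 24 in averaged starvation lost their call. In KO starvation 16 cholangiocyte markers were called lower (mean -0.184, camera adjusted p = 0.0421, adjusted p = 0.48 with an estimated correlation) and 16 red blood cell markers higher (mean 0.164, camera adjusted p = 0.0366, adjusted p = 0.491 with an estimated correlation). The block ended the call of the red blood cell markers (adjusted p = 0.0987), whose mean was -0.156 among narrow arrays. Without KO fed replicate F6 both calls were lost (means of -0.12 and 0.10), as they were without some other arrays. Of 26 stellate cell and fibroblast markers, Sparc, Col6a1 and Pdgfrb fell in averaged starvation (-0.70, -0.31 and -0.30), and 5 fell adjusted over the list alone (list mean -0.19, camera adjusted p = 0.00148, adjusted p = 0.447 with an estimated correlation). Of 23 Kupffer cell and macrophage markers Cd163, a hemoglobin scavenger receptor, rose by 0.56 and the lysozyme Lyz2 fell by 0.79, with no call of the list (mean -0.11, camera adjusted p = 0.312) except without WT starved replicate S3 (mean -0.234, camera adjusted p = 6.72e-05). Markers of neutrophils (mean -0.02), T and NK cells (-0.04) and hepatocytes (-0.00354) were not called, with camera adjusted p of 0.998, 0.697 and 0.942. For hepatocytes the median of 0.04 and the test lay above 0 and the mean below.

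Of the interferon response genes, averaged over genotype, Ifit3 fell by 1.11 (SE 0.28), as did Bst2, which tethers virus particles (-0.98, SE 0.17), and the ubiquitin-like Isg15 (-0.58, SE 0.15); 3 of 37 fell and 0 rose, and 6 fell adjusted over the list alone (mean -0.30, camera adjusted p = 0.000301, adjusted p = 0.598 with an estimated correlation). In KO mice alone 0 of them passed (mean -0.38, camera adjusted p = 3.35e-06, adjusted p = 0.48 with an estimated correlation). In WT mice the list was not called (mean -0.227, camera adjusted p = 0.0579, 15 of 37 above 0), but with array spread as a block it was (adjusted p = 0.00392). It was also called without WT starved replicate S3 (mean -0.505, camera adjusted p = 9.67e-10), WT fed replicate F2 (-0.267) or F4 (-0.228), or KO fed replicate F5, and its mean was -0.093 without WT starved replicate S4 and -0.0839 without replicate 3.

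The 6 wide and 6 narrow arrays, divided at the median spread, differed within groups in 47 histone genes, all higher in narrow arrays, with a median effect of 0.379. This is what a difference in the kind of RNA recovered would give, as is a Spearman correlation of -0.343 between the effect and genomic span across genes. The mean of 29 PPAR-alpha targets was -0.664, lower in narrow arrays in each group (-0.649 in WT fed, -1.25 in WT starved, -0.356 in KO fed and -0.398 in KO starved mice), as a difference in nutritional state between mice would give. Both may apply, and the tests do not separate them. The sets were divided by the spread of these same values, so bright genes tend to lie lower and dim genes higher in narrow arrays. No other genes of equal level were compared, so these effects can partly follow from the division itself.

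Array weights gave 1267 genes between fed KO and WT mice, where equal weights gave 0. Fitted anew to the 9 other splits of these 6 arrays, they gave up to 4930 genes, with 4625, 3979 and 2662 in 3 more and 0 in 5. Weights ran from 0.206 for WT starved replicate 3 to 6.14 for KO fed replicate F5. The 1267 calls could therefore come from the weights themselves.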
